A study of Danio rerio with 12 samples.

How the data were processed

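RNA from pools of 5 zebrafish embryos was measured on 12 one-colour Cy3 Agilent 4x44K zebrafish expression arrays. The arrays fell into 4 groups of 3 by the morpholino (an antisense oligonucleotide that blocks the translation or splicing of its target) injected at the 1-4 cell stage: a control morpholino, a morpholino against Nrf2a, a morpholino against Nrf2b, or both together. Per the labels' protocols the embryos were of the TL strain, were held in 2% DMSO for 4 hours from 48 hours post fertilization, and were sampled at 52 hours. RNA was extracted with RNA STAT-60 and labelled with the Low Input Quick Amp kit, per the labels. Arrays of embryos given tert-butylhydroquinone were not analysed here.

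The authors' scanner files held, per the file headers, background-subtracted and detrended spot intensities from Feature Extraction 10.1.1.1, on a linear scale and not normalized between arrays. A deposited value table held the authors' normalized intensities as whole numbers on a linear scale. Per the labels, the authors had set values under 5 to 5, scaled the arrays by a non-linear curve through rank-invariant probes, removed dim probes by a rule of 2.6 standard deviations, and tested the rest in MeV v4. That test was an ANOVA with p from 1000 permutations and an alpha of 0.01, followed by rank product with 100 permutations and a false discovery rate of at most 10%. The table's log2 values correlated across probes with those of the scanner files at 0.997 to 1.00 on the 12 arrays, and its values were neither centred nor filtered. It was used only as an alternative scaling.

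Each of the 43803 non-control spots was read from the scanner files. Spots marked as outliers by Feature Extraction (4 to 34 per array) were left out, and none was marked as saturated. Processed intensities of replicate spots were averaged on the linear scale, which gave 43603 probes. Values under 5 were then set to 5, and log2 was taken. Each array was scaled to the probe-wise median array by a lowess curve (span 0.2) through rank-invariant probes, with relative rank limits of 0.003 and 0.007. The authors' baseline array and limits were not given in the labels, so these were choices made here. Probes marked well above background on at least 1 array were kept, which left 39670 and removed 3933. The scanner marked 33871 to 38010 probes per array as well above background, and the median processed intensity per array was 246 to 367. Negative control spots had a standard deviation of 1.48 to 5.45 per array, highest on array 1 of the double knockdown. For arrays, precision is limited by their number, 3 per group.

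Probes were given current zebrafish gene symbols through the accessions in the array's annotation and a table of symbols and synonyms, so that 27735 probes carried 1 named gene and 13713 named genes were tested. Probe coordinates are those of the file headers' build, danRer6 (Zv8). Exon and UTR annotation was not used here.

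The model was limma 3.58.1 in R 4.3.3 (tables were handled with data.table, version 1.17.8), with a mean per group over all 12 arrays, empirical Bayes variances and Benjamini-Hochberg adjustment within each contrast. A probe was called at an adjusted p under 0.05. The contrasts were each knockdown minus control, the 3 differences among knockdowns, the interaction (double minus nrf2a, minus the difference of nrf2b and control) and a moderated F-test over the 4 groups. The p-values measure only the spread between these samples, which were pools of 5 embryos, and the labels do not say whether the pools came from separate clutches. For a group whose 3 arrays were all not well above background, the fold is given as a nominal lower bound ("at least"). That bound takes, on each of those arrays, the higher of the probe's own value and the lowest normalized value of any probe marked well above background there. It is not a safe minimum, since unmarked probes could lie above that lowest value. On control array 2, tnfa was unmarked at a log2 of 4.65, where the lowest marked value was 2.69. For saa with nrf2a, the bound of 21.7-fold was close to the fitted 22.75-fold. No fold is given where both groups were dim or the bound was under 1.

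Gene lists were fixed before the data were examined, as were the contrasts, thresholds and alternatives, unless stated otherwise. Of the 32 lists, 1 is not described here, and the others were Nrf2 targets, glutathione transferases, the CNC, Keap1 and Maf family, apoptosis, the proteasome, heat shock and endoplasmic reticulum stress, the aryl hydrocarbon receptor battery, drug metabolism and transport, globins and erythroid genes, heme and iron, the cell cycle, inflammation, the interferon response, the circadian clock, cholesterol synthesis, oxidative phosphorylation, and markers of lens, retina, skeletal muscle, heart, liver, exocrine pancreas, intestine and endocrine cells, neurons, neural progenitors and glia, notochord and cartilage, epidermis, pigment cells, hatching gland, myeloid and lymphoid cells, and endothelium. Each list was tested against the other genes with camera (preset correlation of 0.01) on 1 probe per gene, the brightest, with adjustment over the 32 lists within a contrast. Members were also counted after adjustment over the list alone. With an estimated correlation in place of the preset value, camera called 0 lists in every contrast. The rotation test fry, which asks whether a list's genes move on balance in 1 direction without comparing them with other genes, was an alternative.

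Named genes were chosen by a rule. It took nfe2l2a and nfe2l2b always. For each knockdown minus control and for nrf2b minus nrf2a, it took the 12 largest rises and 12 largest falls among called genes with a symbol that is not a clone or model name and with all 3 arrays of 1 group beyond all 3 of the other. It took the 5 smallest p-values of the interaction, and up to 4 members with the smallest p-values from each list. Where fewer than 12 genes qualified, all were taken, and a gene named in 1 contrast may be given with its value in another.

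The alternatives were 75th percentile scaling, quantile normalization, normexp background correction (offset 50) with quantile normalization, the authors' values, no filter, a filter on all 3 arrays of at least 1 group, the labels' replicate number as a block, the slide as a random block, only the 6 arrays compared in the fit, an adjusted p under 0.10, 1 probe per gene, the authors' own test, and leaving out each array in turn. A filter on all 12 arrays was planned for the comparison of the 3 knockdowns with each other, and was added for the counts after the data were seen. The model was tested on 12 simulated arrays made from each probe's mean over all arrays and its spread pooled over the groups. Known changes were put into the nrf2a arrays in 4 sets of 50 probes among 39602. The changed probes were drawn from those with a mean log2 intensity above 6, so the recovery does not cover dimmer probes. The model recovered 17, 37, 46 and 49 of 50 probes changed by 0.5, 1, 2 and 3 on the log2 scale, with 9 false calls. On random lists camera called the 1 shifted list and 0 of the others. The probes were simulated independently, so this does not test camera on correlated lists such as the neuron markers (estimated correlation of 0.479).

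By the barcodes and scan times in the files, the arrays lay on 6 slides and in 2 scan runs of the same day. The control and nrf2a arrays were in run 1 and the nrf2b and double knockdown arrays in run 2. All control arrays shared 1 slide and all nrf2b arrays another.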

Results

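Gene expression was measured in zebrafish embryos at 52 hours post fertilization after knockdown of Nrf2a, of Nrf2b, or of both. Nrf2 is a transcription factor that turns on antioxidant and detoxifying genes, and zebrafish carry a pair of Nrf2 genes, nfe2l2a and nfe2l2b. The series asks what each of the pair does in the embryo. Morpholinos, antisense oligonucleotides that block translation or splicing of a target RNA, were injected at the 1-4 cell stage, and the embryos analysed here were held in the solvent DMSO from 48 hours. There were 12 arrays of pooled embryos, 3 for each of the control, nrf2a, nrf2b and double knockdown groups, and 39670 probes were tested. Between 33871 and 38010 probes per array were well above background. Arrays of 1 group correlated across probes at a median of 0.990 (12 pairs) and arrays of different groups at 0.988 (54 pairs).

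The target of the Nrf2a morpholino, nfe2l2a, had 2 probes on chromosome 9 (danRer6). The probe at 2647071-2647130 had a log2 intensity of 9.84 ± 0.05 (SD, n = 3) in controls and 9.23 ± 0.16 in the nrf2a knockdown, a difference of -0.61 ± 0.16 (SE, limma adjusted p = 0.0796). The probe at 2646855-2646914 differed by 0.28 ± 0.15 (adjusted p = 0.371), so neither passed the test, and in the double knockdown the differences were 0.09 and 0.30 (adjusted p = 0.831 and 0.399). Against the nrf2a knockdown, the double knockdown differed by 0.70 at the first of these probes (adjusted p = 0.0541). The labels do not say whether the morpholinos block translation or splicing, and a block of translation need not change the RNA level. No tested probe was named nfe2l2b by the array or the gene tables. A transcript that the array describes only as a partial match to a catfish Nrf2, TC416861, had 2 probes at the same place (chromosome 6, 11847490-11847549), and it was singled out from this description after its values were seen. Its first probe was higher in both groups given the Nrf2b morpholino, with 7.97 ± 0.42 (SD) in controls, 8.02 ± 0.46 in the nrf2a knockdown, 9.78 ± 0.09 in the nrf2b knockdown and 9.59 ± 0.45 in the double knockdown. The rise over control was 1.82 ± 0.29 (SE, adjusted p = 0.0381) with nrf2b and 1.62 ± 0.29 (adjusted p = 0.0373) with both, and its second probe gave 1.77 (adjusted p = 0.0548) and 1.55 (adjusted p = 0.0521). Each of these 2 calls held with 4 of the 12 arrays left out in turn. The call with nrf2b held only without nrf2a array 1 or 3 or double knockdown array 2 or 3, and that with both only without control array 3, nrf2a array 1 or 3 or double knockdown array 3, while without each other array the call ended, with the highest adjusted p without control array 1 (0.130 and 0.118). Both groups with the rise were scanned in run 2, so scan run and Nrf2b morpholino cannot be told apart here.

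**Figure D1:**
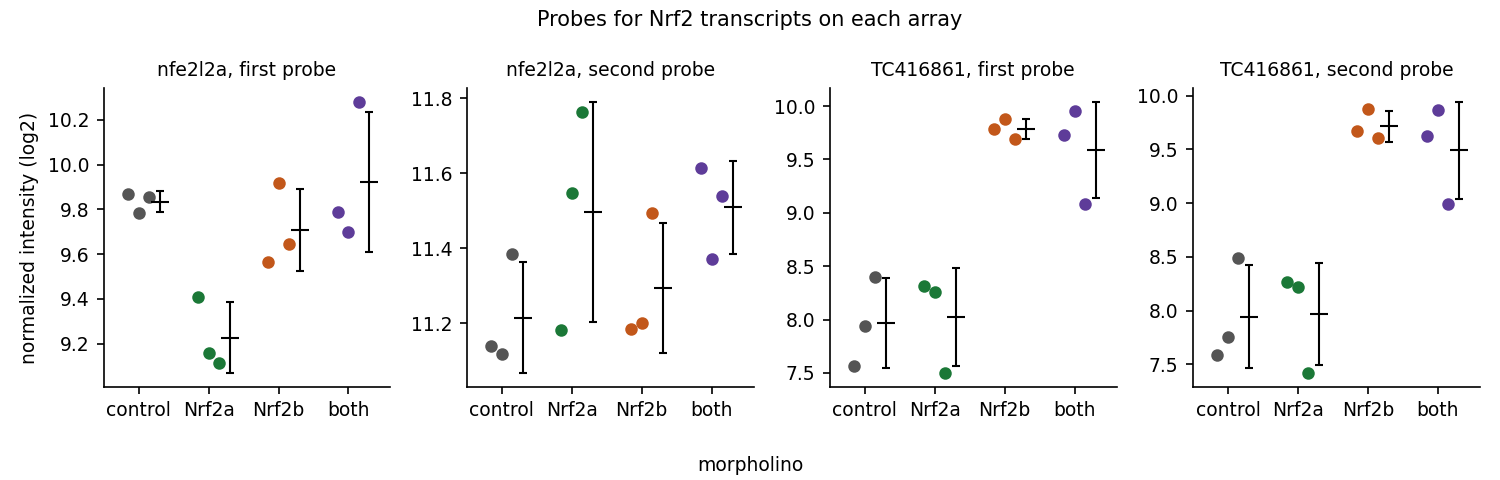
Normalized log2 intensity of the 2 nfe2l2a probes and the 2 TC416861 probes on each of the 12 arrays, by morpholino group, with filled points for arrays where the probe was well above background and bars for the mean ± SD of 3 arrays. The first TC416861 probe averaged 7.97 in controls and 8.02 in the nrf2a knockdown against 9.78 and 9.59 in the groups given the Nrf2b morpholino.

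Across all 4 groups, 1027 probes (252 named genes) differed by limma's moderated F-test, and 8797 had an unadjusted p under 0.05. The authors' own permutation test over the 4 groups, run here on the same values at their alpha, passed 2897 probes where chance would pass 396. Leaving out 1 array moved the count of 1027 by over 1.5 times in most cases: it was 419, 400 or 422 without control array 1, 2 or 3, 342 or 330 without nrf2a array 2 or 3, 485, 579 or 557 without nrf2b array 1, 2 or 3, and 1698 without double knockdown array 3.

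Knockdown of Nrf2a lowered more transcripts than it raised: 648 probes fell and 171 rose against control (168 and 47 named genes). The acute phase protein gene saa (chromosome 7, 11679858-11679917) was at least 21.7-fold lower (adjusted p = 0.00777), since no nrf2a array was well above background. The bilirubin-conjugating enzyme gene ugt1a1 was 17.4-fold lower (adjusted p = 0.0316), with a difference of -4.12 ± 0.79 (SE) on the log2 scale that was -2.91 without nrf2a array 2 and -4.86 without nrf2a array 1, and the alpha-amylase gene amy2al2 was at least 8.19-fold lower (adjusted p = 0.0320). Genes for gamma-crystallins, structural proteins of the fish lens, fell too: crygm2c was 7.21-fold lower (adjusted p = 0.0207) and crygm2b 6.45-fold lower, by 2.69 ± 0.41 on the log2 scale (SE, 3 against 3 arrays, adjusted p = 0.0150). An alpha-globin gene, hbaa2, was 4.79-fold lower (adjusted p = 0.00841).

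The other 6 of the 12 largest falls with a gene name were in dffa, an inhibitor of the apoptotic nuclease (7.62-fold lower), znf366 (4.88-fold), foxq1l, the actin gene acte1 (4.76-fold), the carotenoid-cleaving enzyme gene bco2b, and the cohesin gene smc1a (4.44-fold), with adjusted p of 0.0119 to 0.0313. Rises were smaller. The largest was in cdk5r2b, an activator of neuronal Cdk5, at 4.54-fold (adjusted p = 0.0489), although its other probe had the opposite sign. The collectin gene colec11 rose at least 3.43-fold, lrrc9 3.01-fold and the junctophilin gene jph3b at least 2.54-fold. Among the other rises ppargc1al rose by 1.15, mrpl36 by 1.03 (with its other probe of opposite sign) and mtx1b by 0.85 on the log2 scale. The remaining 5 (lrrc23, mthfsd, agmo, fhit, osbpl11) rose by 0.78 to 0.89.

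Of 34 measured Nrf2 target genes, 2 fell in the nrf2a knockdown and none rose, over all probes and adjusted over the list alone. The peroxidase gene prdx1 (chromosome 2, 4909724-4909783) fell by 0.56 ± 0.09 (SE, adjusted p = 0.0153), and the glutathione S-transferase gene gstp1.2 fell by 0.56 ± 0.10 (adjusted p = 0.0222). The list as a whole was not called (camera adjusted p = 0.308). Of 25 inflammation genes, 24 had a negative difference and 3 fell over all probes and adjusted over the list alone: saa, the cytokine gene tnfa (at least 3.13-fold, with 1 control array well above background, adjusted p = 0.0381) and the chemokine gene ccl34a.4 (by 1.67, adjusted p = 0.0300). The inflammation list was lower than other genes (camera adjusted p = 1.58e-05, adjusted p = 0.858 with an estimated correlation). Of 20 interferon response genes, 3 fell over all probes and 6 adjusted over the list alone (camera adjusted p = 0.00173, adjusted p = 0.858 with an estimated correlation). They were the peptide transporter gene tap1 (by 0.85, adjusted p = 0.0138), the class I light chain gene b2m (by 1.08, adjusted p = 0.0470) and the interferon signalling gene irf9 (by 0.50, adjusted p = 0.0290), whereas isg15 differed by -2.63 and did not pass over all probes (adjusted p = 0.0613).

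Lens markers were lower in the nrf2a knockdown, with 36 of 43 negative and a median of -0.19 on the log2 scale (camera adjusted p = 1.12e-05, adjusted p = 0.858 with an estimated correlation). Of them 3 fell over all probes, crygm2b, crygm2c and the lens filament gene bfsp1 (by 0.54), and 6 adjusted over the list alone. Markers of myeloid and lymphoid cells (33 genes, adjusted p = 0.0243) and of endothelium (30 genes, adjusted p = 0.0440) were lower as lists, with 1 called member, the endothelial diaphragm gene plvapa, which fell by 1.18. Skeletal muscle markers were lower (36 genes, adjusted p = 0.0321) with no called member. Heart (17 genes, adjusted p = 0.0321), neuron (33 genes, adjusted p = 0.0321) and cholesterol synthesis genes (28 genes, adjusted p = 0.0386) were higher as lists. No heart or cholesterol gene was called over all probes, and the only called neuron marker, gad2 of GABA synthesis, fell by 1.05. Adjusted over the list alone, these 6 lists gave 0 heart, muscle and myeloid genes, 1 neuron and 1 endothelial gene (gad2 and plvapa, both lower), and 2 rises and 1 fall among cholesterol genes. With an estimated correlation all 6 had an adjusted p = 0.858 or 0.864. The other 21 lists had an adjusted p of 0.0515 to 0.956. Members of these that passed were gstp1.2 among the glutathione transferases, ugt1a1, amy2al2 and hbaa2, the iron hormone gene hamp (by -1.31), and the cone kinase gene grk7a, which rose by 0.76 ± 0.09 (adjusted p = 0.00871). With each array left out in turn, the inflammation, interferon and lens calls held in all 12 fits. The endothelium call ended without control array 2 or 3, nrf2a array 1 or 2 or nrf2b array 2 or 3 (adjusted p up to 0.195). The neuron call ended without control array 2 or 3 or nrf2a array 2 or 3 (up to 0.478), and the cholesterol call without control array 1 or any nrf2a array (up to 0.222). The muscle call ended without control array 1 or 2 or nrf2a array 3 (up to 0.169), and with 75th percentile scaling (0.209) or quantile normalization (0.107). The heart call ended without control array 1 or nrf2a array 1 or 3 (up to 0.108), and the myeloid call without control array 2 or nrf2a array 2 or 3 (up to 0.0987). With the mean of each gene's probes the heart (0.0728), myeloid (0.159) and endothelium (0.159) calls ended too. The count of 9 called lists was 4 without nrf2a array 3.

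The limma contrast of nrf2a with control called 819 of 39670 probes, with a median size of 0.79 on the log2 scale, and 7145 had an unadjusted p under 0.05. All arrays of 1 group lay beyond all of the other at 24.8% of probes, where chance gives 10%. Both groups were scanned in run 1, but slide parted them completely and cannot be told apart from the knockdown. Their 6 arrays alone gave 65 rises and 578 falls, and 22 of the 36 named calls held there (adjusted p up to 0.133). The count was 94, 116 or 117 without control array 1, 2 or 3, 124 or 160 without nrf2a array 2 or 3, and 515 without nrf2b array 1. Of the 36 named calls, 7, 4 and 4 held without control array 1, 2 or 3 and 17, 7 and 6 without nrf2a array 1, 2 or 3 (adjusted p up to 0.149), while 21, 24 and 26 held without nrf2b array 1, 2 or 3 and 33, 31 and 36 without double knockdown array 1, 2 or 3. Those of saa, hbaa2 and grk7a held in all 12 of these fits, that of prdx1 in 8 and that of gstp1.2 in 6. With the replicate number as a block the count was 319, and the authors' own pair of tests called 209.

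**Figure D2:**
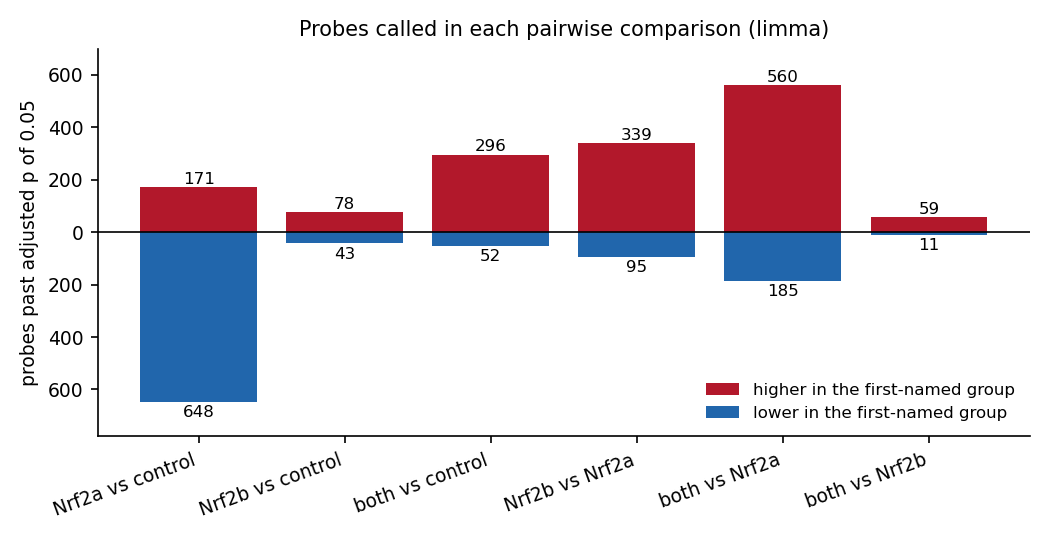
Number of probes called up or down by limma (adjusted p under 0.05) in each of the 6 differences between groups, among 39670 tested probes, as 1 bar per direction. The nrf2a knockdown had 171 rises and 648 falls against control, the nrf2b knockdown 78 and 43, and the double knockdown 296 and 52.

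After knockdown of Nrf2b, limma called 78 probes up and 43 down against control. The heme-degrading oxygenase gene hmox1a rose 2.55-fold, by 1.35 ± 0.21 on the log2 scale (SE, 3 against 3 arrays, adjusted p = 0.0329), and it was the only 1 of 34 measured Nrf2 target genes to pass, over all probes or adjusted over the list alone. The T cell coreceptor gene cd4-1 rose 2.61-fold (adjusted p = 0.0137), the elastase gene cela1.5 2.82-fold (adjusted p = 0.0156), the interferon gamma-related gene ifng1r at least 2.86-fold (adjusted p = 0.0215), and the odorant receptor gene or71ar1 at least 4.07-fold (adjusted p = 0.0203). Falls included saa, at least 30.3-fold (adjusted p = 0.0138), and cfbl, related to complement factor B, 3.28-fold (adjusted p = 0.0156).

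Among the other rises were uck1, a kinase of pyrimidine nucleoside salvage (2.20-fold, adjusted p = 0.0229), mtx1b (by 1.11), reep6 (by 1.02), the lipoxygenase gene alox5b.3 (by 1.01), the thyroid hormone transporter gene slco1c1 (by 1.01), ush1ga and lrit1b, with adjusted p of 0.0215 to 0.0371. The TRIM family gene btr31 was 3.06-fold lower (adjusted p = 0.0156) and the interferon-induced gene xaf1 2.95-fold lower (adjusted p = 0.0499). The GDF15 receptor gene gfral (adjusted p = 0.0206) was lower, the dynein heavy chain gene dync1h1 fell by 0.83 (adjusted p = 0.0215) and the matricellular gene ccn5 by 0.55 (adjusted p = 0.0388). The other 4 falls (rph3ab, niban1a, nceh1a, entpd5a) had an adjusted p of 0.0386 to 0.0480.

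Proteasome subunit genes were higher as a list in the nrf2b knockdown, 31 of 37 being positive with a median of 0.12 on the log2 scale (camera adjusted p = 5.66e-05, adjusted p = 0.626 with an estimated correlation). None passed alone, over all probes or adjusted over the list alone. Cell cycle genes were higher too (33 of 42 positive, adjusted p = 2.01e-04), with 0 called over all probes and 2 rises adjusted over the list alone, cdc20 at 0.43 and cdk1 at 0.50. Inflammation genes were lower (20 of 25 negative, adjusted p = 0.00664), 1 over all probes (saa) and 4 adjusted over the list alone. Interferon genes were lower (14 of 20 negative, adjusted p = 0.0378), 0 over all probes and 4 adjusted over the list alone, among them tap1 at -0.53 and b2m at -1.19. Oxidative phosphorylation (34 genes, adjusted p = 0.0208) and liver (30 genes, adjusted p = 0.0462) were higher as lists, and notochord and cartilage (25 genes, adjusted p = 0.0378), myeloid and lymphoid cells (adjusted p = 0.0208) and endothelium (adjusted p = 0.0123) were lower. None of their members passed over all probes, and adjusted over the list alone 1 oxidative phosphorylation gene (cox7b), 3 higher and 7 lower myeloid genes and 2 lower endothelial genes (fli1rs, tek) did. All 9 calls had an adjusted p = 0.626 with an estimated correlation. The Nrf2 target list was not called (adjusted p = 0.170), and the other 21 uncalled lists had an adjusted p of 0.0884 to 0.880. With each array left out in turn, the proteasome, cell cycle and endothelium calls held. The inflammation call ended without control array 3 or nrf2b array 2 (up to 0.153), and the interferon and oxidative phosphorylation calls without control array 3 or nrf2b array 1 (up to 0.262 and 0.0893). The liver call ended without control array 2 or 3, double knockdown array 2 or 3 or nrf2b array 1 (up to 0.250), the notochord call without control array 1 or 2 or nrf2b array 2 (up to 0.157), and the myeloid call without control array 2 or nrf2b array 2 (up to 0.138). The liver call also ended with 75th percentile scaling (0.0659), and it and the notochord call with the replicate number as a block (both 0.0512). The count of 9 called lists was 14 without nrf2b array 3.

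The nrf2b contrast called 121 probes (24 named genes up, 11 down) with a median size of 1.00 on the log2 scale, and 5953 had an unadjusted p under 0.05. Groups were fully separated at 25.5% of probes, against 10% by chance. The count was 22, 36 or 36 without control array 1, 2 or 3, 31, 4 or 21 without nrf2b array 1, 2 or 3, and 319 without double knockdown array 3. Falls outnumbered rises without control array 1 (13 and 9) or 2 (21 and 15) or nrf2b array 1 (17 and 14), and equalled them without control array 3 (18 and 18) or nrf2b array 2 (2 and 2). Of the 24 named calls, 3, 7 and 6 held without control array 1, 2 or 3 and 4, 2 and 4 without nrf2b array 1, 2 or 3 (adjusted p up to 0.149), while 19, 16 and 14 held without nrf2a array 1, 2 or 3 and 19, 19 and 24 without double knockdown array 1, 2 or 3. That of cd4-1 held in all 12 of these fits and that of hmox1a in 4 (adjusted p up to 0.105). The 6 arrays alone gave 30 probes, with 8 of the 24 named calls kept (adjusted p up to 0.117), the replicate block 50, and the authors' own pair of tests 244, against 209 for nrf2a, where limma called 819. Slide and scan run both parted these groups completely, so neither can be told apart from the knockdown.

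In the double knockdown, 296 probes rose and 52 fell against control (68 and 17 named genes). The heme oxygenase gene hmox1a rose 2.54-fold, by 1.35 ± 0.21 on the log2 scale (SE, 3 against 3 arrays, adjusted p = 0.0212), while prdx1 fell by 0.47 ± 0.09 (adjusted p = 0.0391). The tryptophan-degrading enzyme gene ido1 rose at least 4.81-fold (adjusted p = 0.0212), the desmosome gene pkp2 4.31-fold (adjusted p = 0.0218), the ultraviolet opsin gene opn1sw1 4.13-fold (adjusted p = 0.0226) and the peptidoglycan recognition gene pglyrp6 3.09-fold (adjusted p = 0.00715). Among the falls were ddx4, which encodes the germ cell helicase Vasa, at least 1.95-fold (adjusted p = 0.0414), the germ cell gene nanos3, 2.01-fold (adjusted p = 0.0380), and the egg coat gene zp2.2, 1.93-fold (adjusted p = 0.0380).

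Other rises were in the elastin gene elnb (at least 4.66-fold), the odorant receptor genes or63b1 (at least 3.77-fold) and or71ar1 (at least 3.24-fold), cbln8 (at least 3.22-fold), the myostatin gene mstna (at least 3.13-fold), the collagen hydroxylase gene p4ha3 (3.12-fold) and olfcb1 (at least 3.02-fold), with adjusted p of 0.0197 to 0.0487. The oxytocin receptor gene oxtra passed too (adjusted p = 0.0361), but both groups were not well above background. Other falls were in saa (by 2.82 on the log2 scale, adjusted p = 0.0373, with -2.17 without double knockdown array 3), btr31 (by 1.13), dync1h1 (by 0.56), ccl39.3 (by 1.23), mast3b (at least 1.16-fold), niban1b (at least 1.05-fold), nceh1a (dim in the knockdown, with no fold), fgf17 (by 0.63) and gaa2 (by 0.59). For saa, 1 of 3 double knockdown arrays was well above background, so the size of its fall is uncertain.

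Of 34 Nrf2 targets, 1 rose (hmox1a) and 1 fell (prdx1), over all probes and adjusted over the list alone, and the list was not called (camera adjusted p = 0.673). Globin and erythroid genes were lower as a list (20 of 24 negative, adjusted p = 0.0187, adjusted p = 0.957 with an estimated correlation), with 0 called over all probes and 2 falls adjusted over the list alone, hbaa2 (adjusted p = 0.132 over all probes) and hbbe1.1 at -0.29. Heart markers were higher (13 of 17 positive, adjusted p = 0.0133, adjusted p = 0.957 with an estimated correlation), with 0 called over all probes and 2 rises adjusted over the list alone, myh7 at 0.63 and tnni1b at 0.71. Epidermis markers were higher (22 of 28 positive, adjusted p = 0.0133, adjusted p = 0.852 with an estimated correlation, fry adjusted p = 0.0389), with 1 rise over all probes, the annexin gene anxa2a at 0.84 ± 0.15 (adjusted p = 0.0380), and 7 adjusted over the list alone. The epidermis call ended with 75th percentile scaling (adjusted p = 0.491, with 9.58e-04 to 0.852 over its alternatives). Inflammation and interferon lists were not called (adjusted p = 0.255 and 0.708), and the other 25 lists had an adjusted p of 0.140 to 0.957. With each array left out in turn, the heart and epidermis calls held, and the globin call ended without control array 3 or double knockdown array 3 (up to 0.294). The count of 3 called lists was 7 or 5 without control array 1 or 3 and 6 or 5 without double knockdown array 1 or 3.

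The double knockdown contrast called 348 probes with a median size of 0.95 on the log2 scale, and 6001 had an unadjusted p under 0.05. Groups were fully separated at 20.7% of probes, against 10% by chance. The count was 68, 127 or 145 without control array 1, 2 or 3, 147, 193 or 937 without double knockdown array 1, 2 or 3, and 226 without nrf2b array 1. Of the 28 named calls, 1, 5 and 8 held without control array 1, 2 or 3 and 3, 4 and 19 without double knockdown array 1, 2 or 3 (adjusted p up to 0.156), while 16, 13 and 17 held without nrf2a array 1, 2 or 3 and 12, 15 and 14 without nrf2b array 1, 2 or 3. That of pglyrp6 held in all 12 of these fits, that of hmox1a in 8 (adjusted p up to 0.0707) and that of prdx1 in 1 (up to 0.131). With only these 6 arrays in the fit 13 probes were called and 0 of the 28 named calls held (adjusted p up to 0.202), the replicate block gave 166 probes, and the authors' own pair of tests 201. Slide and scan run both parted these groups completely, so neither can be told apart from the knockdown.

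Compared directly, Nrf2 target genes were higher after Nrf2b than after Nrf2a knockdown: of 34, 5 were higher over all probes, none was lower, and 7 were higher adjusted over the list alone (camera adjusted p = 0.0329, adjusted p = 0.665 with an estimated correlation). The gene prdx1 was 1.62-fold higher (0.70 ± 0.09 on the log2 scale, SE, 3 against 3 arrays, adjusted p = 0.0173), gstp1.2 1.59-fold (adjusted p = 0.0215) and hmox1a 2.33-fold (adjusted p = 0.0295). Glutathione reductase, gsr, was higher by 0.46 (adjusted p = 0.0460) and the redox-sensitive regulator gene pir by 0.39 (adjusted p = 0.0433). The lens crystallin gene crygm1 was 3.13-fold higher (adjusted p = 0.00973), ugt1a1 higher by 4.17 (adjusted p = 0.0432, with 2.96 without nrf2a array 2 and 4.91 without nrf2a array 1) and hbaa2 2.79-fold higher (adjusted p = 0.0364), while the germ cell genes nanos3 and ddx4 were lower by 1.06 and 1.23 (adjusted p = 0.0299 and 0.0480). The probe of ddx4 was well above background on 1 of 3 nrf2b arrays.

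Other genes higher after Nrf2b knockdown were the lysyl oxidase gene loxl3a (3.77-fold), cela1.4 (by 1.71), smc1a (by 1.56), ifng1r (at least 2.79-fold), dnm2b (by 1.52), the galectin gene lgals1l1 (by 1.47), uck1 (by 1.40), the sialidase gene neu3.4 (at least 2.35-fold) and the potassium channel gene kcnk13b (by 1.36). Genes lower were lrrc9 (at least 3.84-fold), sugct (at least 2.41-fold), ppargc1al, osbpl11, the vitronectin gene vtnb, gaa2, the relaxin family gene insl5a, entpd5a, gsk3ba and otud7a, the last 8 by 0.71 to 1.16.

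Lens markers were higher after Nrf2b than after Nrf2a knockdown (37 of 43 positive, camera adjusted p = 4.1e-05), 1 over all probes (crybb2, by 0.81, adjusted p = 0.0466) and 4 adjusted over the list alone. Cell cycle genes were higher (33 of 42 positive, adjusted p = 4.1e-05), 1 both ways, the mitotic kinase gene aurkb (by 0.39, adjusted p = 0.0386). Proteasome (31 of 37 positive, adjusted p = 0.0329) and oxidative phosphorylation genes (30 of 34 positive, adjusted p = 0.0230) were higher as lists and heart (12 of 17 negative, adjusted p = 0.0230) and neuron markers (29 of 33 negative, adjusted p = 9.46e-04) lower, with 0 called members either way. These 6 calls had an adjusted p = 0.665 with an estimated correlation. Called members of the other 24 lists (adjusted p of 0.0504 to 0.950) included the recombinase gene rag2 (higher by 0.97), cybb of the phagocyte oxidase (by 0.63), irf9 (by 0.61) and the myelin gene plp1b (by 0.68), and the clock gene cry1a, lower by 0.65. With each array left out in turn the lens and cell cycle calls held, and the neuron call ended without nrf2a array 3 (0.0564). The Nrf2 target call ended without nrf2a array 3, double knockdown array 3 or nrf2b array 1 or 2 (up to 0.117), and that of the proteasome without nrf2a array 2 or 3 or nrf2b array 2 (up to 0.193). The oxidative phosphorylation call ended without nrf2a array 3 or nrf2b array 1 (up to 0.0630) and the heart call without nrf2a array 1 or 3 or nrf2b array 3 (up to 0.240). With 75th percentile scaling the Nrf2 target (0.0997), proteasome (0.359) and oxidative phosphorylation (0.320) calls ended. The count of 8 called lists, 1 of which is not described here, was 3 without nrf2a array 3 and 5 without nrf2b array 1.

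This contrast called 434 probes, 339 higher and 95 lower after Nrf2b knockdown (91 and 26 named genes), and 6846 had an unadjusted p under 0.05. Groups were fully separated at 23.3% of probes, against 10% by chance. Without nrf2b array 1, limma called 0 probes, and 5447 had an unadjusted p under 0.05. The count was 52 or 49 without nrf2b array 2 or 3, 26 or 9 without nrf2a array 2 or 3, 281, 188 or 221 without control array 1, 2 or 3, and 943 without double knockdown array 3. Of the 36 named calls, 0, 5 and 5 held without nrf2b array 1, 2 or 3 and 22, 3 and 1 without nrf2a array 1, 2 or 3 (adjusted p up to 0.152), while 23, 18 and 20 held without control array 1, 2 or 3 and 31, 25 and 36 without double knockdown array 1, 2 or 3. With the replicate block the count was 74, with the authors' own pair of tests 239. With only these 6 arrays in the fit 19 of the 36 named calls held (adjusted p up to 0.133). Slide and scan run both parted these groups too, so neither can be told apart from the difference.

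Adding the Nrf2b morpholino to the Nrf2a morpholino raised 560 probes and lowered 185 relative to Nrf2a knockdown alone (150 and 61 named genes). The alpha-amylase gene amy2al2 rose at least 17.9-fold (adjusted p = 0.0132), since no nrf2a array was well above background, and at least 32.4-fold without double knockdown array 3. The receptor gene gfral rose by 1.74 ± 0.17 on the log2 scale (SE, 3 against 3 arrays, adjusted p = 0.00235), hmox1a by 1.22 (adjusted p = 0.0248) and the lens genes crygm2b and crygm2c by 2.07 and 2.25 (adjusted p = 0.0367 and 0.0478). The germ cell gene nanos3 fell by 1.47 (adjusted p = 0.00766) and ddx4 at least 2.34-fold (adjusted p = 0.0176). The count of 745 was 485 without control array 2, 208 or 159 without nrf2a array 2 or 3, 410 without double knockdown array 1 and 464 without nrf2b array 1. With each array left out in turn the calls of amy2al2, gfral and nanos3 held in all 12 fits, that of ddx4 in 10, of hmox1a in 9, of crygm2b in 3 and of crygm2c in 1 (adjusted p up to 0.0965). The replicate block gave 327 probes and ended the calls of crygm2b and crygm2c (adjusted p = 0.0692 and 0.0762). The 6 arrays alone gave 28 probes, with gfral alone of these 7 genes kept (adjusted p up to 0.195), and the authors' own pair of tests 207, with 94 up and 113 down. Slide and scan run both parted these groups completely, so neither can be told apart from the difference.

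Adding the Nrf2a morpholino to the Nrf2b morpholino changed fewer probes, 59 up and 11 down (14 and 5 named genes). The peroxidase gene prdx1 fell by 0.61 ± 0.09 (SE, 3 against 3 arrays, adjusted p = 0.0295), and gstp1.2 differed by -0.43 without passing (adjusted p = 0.165). The gene amy2al2 rose at least 21.1-fold (adjusted p = 0.0267), and at least 38.3-fold without double knockdown array 3. The genes gfral and pglyrp6 rose by 1.81 and 1.69 (adjusted p = 0.00338 and 0.00745), and hmox1a differed by -0.01 (adjusted p = 0.996). For pglyrp6, 1 of 3 nrf2b arrays was well above background, so the size of its rise is uncertain. Both groups were scanned in run 2, but slide parted them completely and cannot be told apart from the difference. Their 6 arrays alone gave 7 probes and none of these 4 calls (adjusted p up to 0.266). With each array left out in turn the calls of gfral and pglyrp6 held in all 12 fits, that of prdx1 in 4 (adjusted p up to 0.108) and that of amy2al2 in 3 (up to 0.0973). The replicate block ended those of prdx1 and amy2al2 (adjusted p = 0.0643 and 0.0826). The count of 70 was 29 without control array 3, 41 or 34 without nrf2a array 2 or 3, 31, 39 or 125 without double knockdown array 1, 2 or 3, and 22 without nrf2b array 2. The replicate block gave 34 and the authors' own pair of tests 149.

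**Figure D3:**
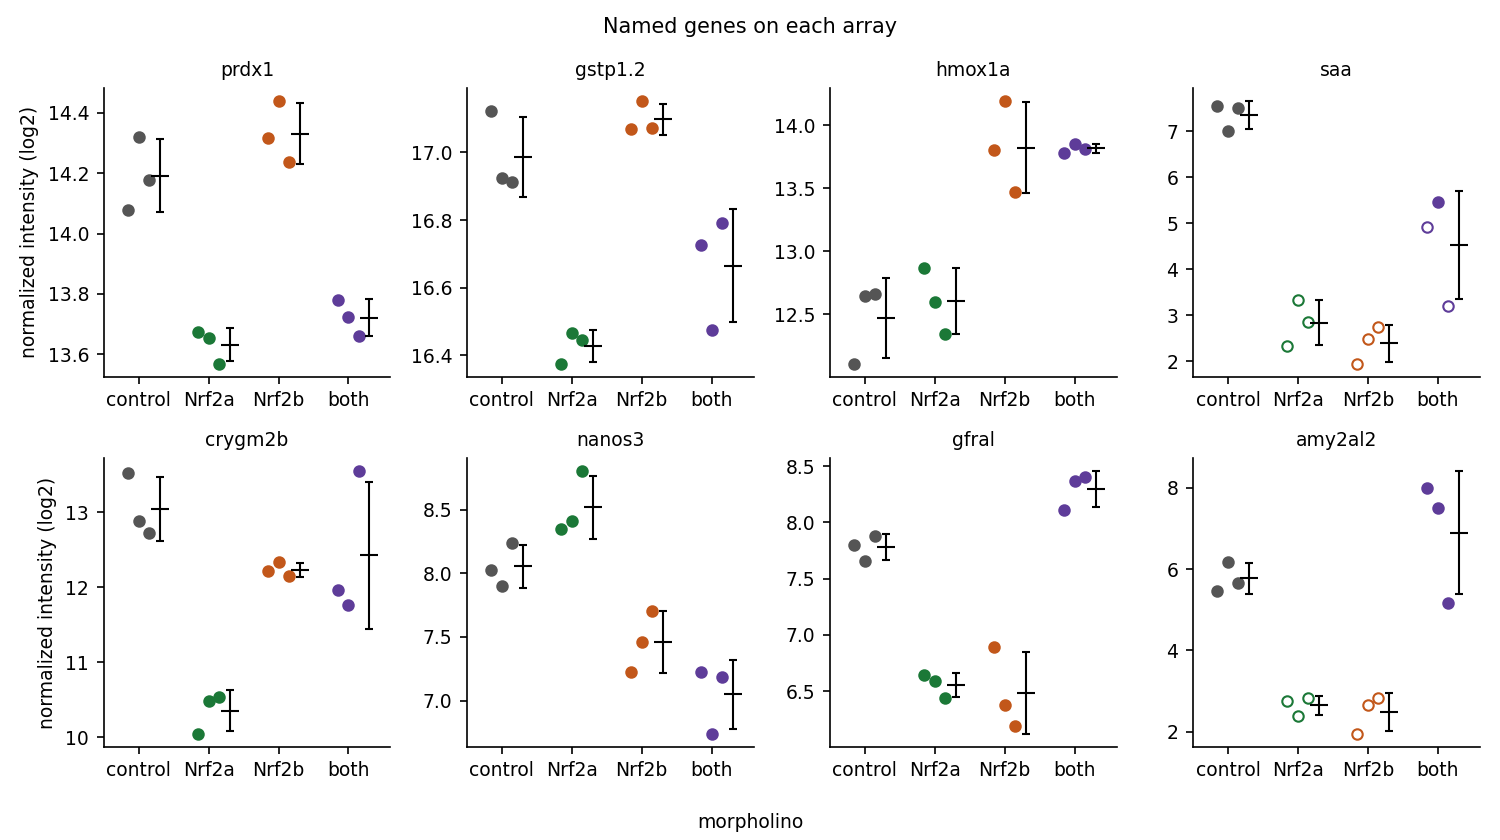
Normalized log2 intensity of 8 named genes on each of the 12 arrays, by morpholino group, with filled points for arrays where the probe was well above background, open points where it was not, and bars for the mean ± SD of 3 arrays. The probe of amy2al2 averaged 5.77 in controls, 2.66 and 2.49 in the nrf2a and nrf2b knockdowns, and 6.90 in the double knockdown.

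The interaction asked whether the Nrf2a and Nrf2b morpholinos together did what the sum of their separate log2 effects would give. For 90 probes the double knockdown lay above that sum and for 15 below it (24 and 7 named genes). The GDF15 receptor gene gfral lay above it by 3.04 ± 0.23 on the log2 scale (SE, 12 arrays, adjusted p = 0.00261). The mean log2 intensity of gfral was 7.78 in controls, 6.56 and 6.48 in the single knockdowns and 8.30 in the double knockdown. The matricellular gene ccn5 lay above it by 1.33 ± 0.12 (adjusted p = 0.00499). The taste receptor gene tas2r203 passed as well (adjusted p = 0.00699) but was well above background on 3 of 12 arrays. The genes saa and amy2al2 passed (adjusted p = 0.00806 and 0.0122), but no array of either single knockdown was well above background for them, and the sums of their separate effects, log2 values of -2.11 and -0.628, lay under the lowest value on any array (1.865), so the double knockdown had to lie above. The sum lay under that value for 16 of the 90 probes above it, while 64 of the 105 called probes were well above background on all 12 arrays (53 above the sum and 11 below). For hmox1a and prdx1 the interaction was -0.14 and -0.05 and did not pass (adjusted p = 0.848 and 0.864).

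The interaction contrast called 105 probes, and 6256 had an unadjusted p under 0.05. The count was 33, 37 or 24 without control array 1, 2 or 3, 55, 29 or 30 without nrf2a array 1, 2 or 3, 42, 29 or 24 without nrf2b array 1, 2 or 3, and 56, 69 or 236 without double knockdown array 1, 2 or 3, while the 5 named calls held in all of these fits (adjusted p up to 0.0407). With the replicate block the count was 24, with normexp correction 62, where the calls of amy2al2 (adjusted p = 0.0655) and tas2r203 (adjusted p = 0.107) ended, and without a filter 67. Slide parted all the groups completely, so it cannot be told apart from an interaction.

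The 3 knockdowns were also set against each other by their log2 differences from the same 3 control arrays, over 39602 probes. Between the nrf2b and double knockdowns 58 probes rose in both where independent lists would share 0.574, and 13 fell in both (0.0565 by independence). Between the nrf2a and nrf2b knockdowns 7 rose in both (0.331) and 21 fell in both (0.700), and between the nrf2a and double knockdowns 17 rose (1.27) and 23 fell in both (0.847). The called probes went opposite ways in 0, 0 and 2 cases. Covariances were 0.0784 for nrf2a with nrf2b, 0.0711 for nrf2a with both and 0.0838 for nrf2b with both, beside 0.0411, 0.0410 and 0.0410 simulated for unchanged groups against the same controls, and correlations were 0.540, 0.477 and 0.600 beside 0.555, 0.529 and 0.523. Part of any excess may come from the shared controls, since 3 arrays cannot be split into separate sets of 2. The nrf2b and double knockdown arrays were scanned in run 2 and the controls in run 1. A run difference would enter both of their contrasts alike, so for this pair it cannot be told apart from a shared effect. All control arrays shared 1 slide that held no other group. A difference of that slide would enter all 3 contrasts alike, so for no pair can it be told apart from a shared effect. Neither the simulated values nor those for independent lists allow for a run or slide difference. On the 32920 probes well above background on all 12 arrays the covariances were 0.0375, 0.0348 and 0.0422, beside 0.0158, 0.0158 and 0.0157 simulated for unchanged groups.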

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

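The tests of scan run and control slide for the immune genes, of scan run and of a morpholino effect for TC416861, and of the share of lens tissue were chosen only after the result was seen.

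The joint effect of the Nrf2a and Nrf2b morpholinos differed from the sum of their separate effects, by limma's test of the interaction itself, at 105 probes. Slide parted the groups completely, so slide differences cannot be told apart from this interaction. The GDF15 receptor gene gfral had an interaction of 3.04 ± 0.23 on the log2 scale (SE, adjusted p = 0.00261, and up to 0.0192 over the alternatives). The matricellular gene ccn5 had 1.33 ± 0.12 (adjusted p = 0.00499, up to 0.0263), with a mean of 8.72 in controls, 7.63 with nrf2a, 8.17 with nrf2b and 8.42 with both. The taste receptor gene tas2r203, well above background on 3 of 12 arrays, had a fitted value of 2.03 (adjusted p = 0.00699, up to 0.107), with means of 3.74, 3.61, 3.22 and 5.12. The acute phase gene saa had a fitted value of 6.64 (adjusted p = 0.00806, up to 0.0401) and the amylase gene amy2al2 of 7.52 (adjusted p = 0.0122, up to 0.0655). For both, no array of either single knockdown was well above background and the sum of the separate effects lay under the lowest value on any array, so the positive sign was fixed in advance and these are not measured sizes.

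Both TC416861 probes, described on the array as a partial match to a catfish Nrf2, were higher in each of the groups given the Nrf2b morpholino. A scan run difference that shifts all probes of like brightness is argued against, since on values scaled by 1 factor per array, which leave such a shift in place, the median difference between runs was 0.0174 over 4058 probes of like brightness, beside 1.68 for TC416861. The smallest of 8 differences over the 2 probes was 1.53, which restates the rise that singled the probes out and does not argue for an effect of the Nrf2b morpholino. Scan run and Nrf2b morpholino fall on the same arrays, so such an effect and a run difference particular to these probes cannot be told apart. Whether TC416861 is the RNA that the Nrf2b morpholino targets was not tested.

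Inflammation and interferon genes were lower in each single knockdown than in controls, with medians over 45 genes of -0.38 for nrf2a, -0.24 for nrf2b and 0.107 for the double knockdown, the last being -0.028, 0.008 or 0.298 without control array 1, 2 or 3. A single control array with raised immune genes is argued against as the whole cause, since the highest of the 6 single knockdown medians with 1 control array left out was -0.127 (nrf2b, without control array 3). Part of the difference rested on that array. Without it the nrf2a median was -0.248, and camera no longer called the inflammation and interferon lists in nrf2b. A difference between scan runs is argued against for nrf2a by the design alone, since the control and nrf2a arrays lay in 1 scan run. For nrf2b 0 runs held both groups, so run and knockdown cannot be told apart. All control arrays shared 1 slide, so slide and control group cannot be told apart either, and an effect of the knockdowns themselves stays open as a hypothesis.

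Lens crystallin genes were lower in the nrf2a knockdown, with falls of 7.21-fold in crygm2c and 6.45-fold in crygm2b. A lower share of lens tissue as the whole cause is argued against, since the 33 brighter lens markers had a median of -0.176 (95% interval -0.224 to -0.122), far from the change in these genes, and 5 were at or above 0. That interval comes from resampling the genes on the same 6 arrays. It treats the genes as independent and leaves out the spread between arrays. Over all 43 lens markers the lowest median with 1 array left out was -0.236 (without nrf2a array 3). A single array as the cause is argued against too, since the highest median over the 43 lens markers with each of the 6 arrays left out was -0.118 (without nrf2a array 1). An effect of the Nrf2a morpholino itself was not tested apart from these and stays open.

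Other ways of grouping the same arrays were counted for each result. Over 100 drawn splits of the 12 arrays into 4 groups of 3, the real split alone (1 of 100) reached 1027 probes in the F-test. The highest other gave 35, so chance is argued against for a difference among the groups. In the interaction 1 of 100 reached 105, where the highest other gave 7. These counts cannot decide on the interaction, since the drawn groups mix arrays of groups that differ, which widens the spread within them. For contrasts of 3 against 3 arrays, 10 splits are too few for a share under 0.05. The real split gave 819 probes for nrf2a, 121 for nrf2b and 348 for both against control, where the highest others gave 0, 2 and 1 (limma, all 12 arrays in the fit). It gave 434 for nrf2b against nrf2a, 745 for double against nrf2a and 70 for double against nrf2b, where the highest others gave 2, 2 and 3. Lists called by camera numbered 9, 9, 3 and 8 in nrf2a, nrf2b and double against control and nrf2b against nrf2a, where the highest others gave 8, 13, 13 and 8, and 1, 3, 8 and 2 of the 10 splits gave as many.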

How the results depend on the processing

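The filter on probes well above background on all 12 arrays was chosen for the counts only after the result was seen. Counts below are in the order F-test, nrf2a, nrf2b and double against control, nrf2b against nrf2a, double against nrf2a, double against nrf2b, and interaction, where limma called 1027, 819, 121, 348, 434, 745, 70 and 105 probes. Leaving out each array in turn gave ranges of 330 to 1698, 94 to 1192, 4 to 319, 68 to 937, 0 to 943, 159 to 803, 22 to 125, and 24 to 236. Where this left 2 arrays in a group the spread was pooled with the other groups. With the replicate number as a block the counts were 374, 319, 50, 166, 74, 327, 34 and 24. The numbers did not pair the arrays, since 0 of 18 pairs with the same number correlated over 0.1 after removal of the group means and 3 of 12 arrays correlated best with an array of their own number, so this block spends degrees of freedom. With only the 6 arrays compared in the fit, counts beyond 1.5 times were 30 for nrf2b and 13 for double against control, 28 for double against nrf2a and 7 for double against nrf2b, a fit with fewer arrays to estimate the spread. An adjusted p under 0.10 gave 2458, 1851, 443, 798, 1428, 1999, 123 and 377, a looser limit by construction. With 1 probe per named gene, fewer were tested, and the counts were 249, 212, 44, 42, 132, 219, 17 and 35. Normexp correction gave 24 for double against nrf2b and 62 for the interaction, and no filter gave 67 for the interaction. The filter on all 12 arrays gave 663 for nrf2b against nrf2a and 32 for double against nrf2b. The cause was not tested for these 5 counts. The authors' own test over the 4 groups passed 2897 probes (839 after Benjamini-Hochberg adjustment at 0.05), and with rank product it called 209, 244, 201, 239, 207 and 149 probes in the 6 differences between groups, of which limma also called 163, 71, 108, 118, 127 and 40. The cause was not tested. With 75th percentile scaling, quantile normalization, the authors' values, the slide as a random block or a filter on all 3 arrays of at least 1 group, no count moved beyond 1.5 times, and no scaling moved the share of rises by over 9.8 percentage points. Since slide parted the groups completely, the random block could not remove a slide difference between groups. All arrays were scanned on 1 day, so a scan date block was not run.

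Camera called 9, 9, 3 and 8 lists for nrf2a, nrf2b and double against control and nrf2b against nrf2a. Leaving out each array gave 4 to 10, 6 to 14, 3 to 7 and 3 to 11. An estimated correlation gave 0, 0, 0 and 0, fry gave 0, 0, 1 and 0, and 75th percentile scaling gave 4 for nrf2b against nrf2a. The estimated correlations of the called lists were 0.040 (epidermis) to 0.479 (neurons), all above the preset 0.01. Camera allows a wider spread for a higher correlation, so the calls with the preset value are the less cautious. For fry and the scaling the cause was not tested. Of the 29 list calls, 22 held with 75th percentile scaling, 28 with quantile normalization, 27 with the replicate block and 25 with the mean of each gene's probes, and the direction held in all of these.

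Covariances between the knockdowns' differences from control ranged from 0.0841 to 0.108 for nrf2a with nrf2b, 0.0786 to 0.1005 for nrf2a with both and 0.0895 to 0.112 for nrf2b with both when a control array was left out, beside 0.0494 to 0.0688 simulated for unchanged groups. They were 0.0375, 0.0348 and 0.0422 on probes well above background on all 12 arrays, beside 0.0157 to 0.0158 simulated. The cause was not tested.

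Named genes gave 217 results, 129 of them called. Direction turned in 10 of 4751 alternatives, all at probes of nfe2l2a or TC416861 in contrasts where they were not called, and the cause was not tested. For genes chosen with all arrays of 1 group beyond all of the other, leaving out an array could not turn the direction. Fits that change only the spread, the filter or the limit leave the difference as it is. This count therefore says little about stability. For TC416861 in nrf2a against control the first probe gave -0.15 without control array 1, -0.09 without nrf2a array 1 and -0.06 without nrf2a array 2, and the second gave -0.15 and -0.07 without control arrays 1 and 2, -0.13 and -0.10 without nrf2a arrays 1 and 2, and -0.0128 with the authors' values, and the highest values were 0.32 and 0.30, both without nrf2a array 3. For nfe2l2a, the first probe gave -0.0903 in double against control without double knockdown array 3 and at most 0.20 (without array 2), and the second gave -0.0212 in nrf2b against control without nrf2b array 3 and at most 0.16 (without control array 3). Of the 217 results, 27 calls ended and 3 began with 75th percentile scaling, 11 and 1 with quantile normalization, 40 and 14 with normexp correction, 14 and 4 with the authors' values, 26 and 0 with no filter, 8 and 0 with the slide as a random block, and 87 and 0 with the replicate block. With only the 6 arrays compared in the fit, 75 calls ended and 5 began, the calls kept being 22 of 36 for nrf2a, 8 of 24 for nrf2b and 0 of 28 for double against control and 19 of 36 for nrf2b against nrf2a. Dim probes limit the size of the largest folds, which are nominal bounds, not safe minimum folds, wherever no array of a group was well above background.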

Other observations

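The tests of gene lists in the interaction and in the double knockdown against each single knockdown were chosen only after the result was seen. Slide parted all the groups compared, so it cannot be told apart from these differences. Inflammation genes lay above the sum of the separate effects in the double knockdown, with a median interaction of 0.76 on the log2 scale over 25 genes (camera adjusted p = 3.85e-10, adjusted p = 0.503 with an estimated correlation). Dim members such as saa had to lie above it, and over the 21 genes whose sum could be measured the median was 0.69 (adjusted p = 4.22e-07, adjusted p = 0.667 with an estimated correlation). Interferon response genes (17 such genes, median 0.48, adjusted p = 3.97e-04, adjusted p = 0.667 with an estimated correlation) and lens markers (median 0.26, adjusted p = 2.78e-06, adjusted p = 0.688 with an estimated correlation) lay above it too. Proteasome genes lay below it (median -0.18, adjusted p = 5.16e-05, adjusted p = 0.688 with an estimated correlation). Cell cycle genes were lower in the double knockdown than with nrf2b alone (median -0.17, adjusted p = 4.59e-08, adjusted p = 0.449 with an estimated correlation). The cytokine gene tnfa was higher in the double knockdown than with nrf2a alone at least 4.16-fold (adjusted p = 0.0226), with no nrf2a array well above background. This call held in 9 of the 12 fits with an array left out (adjusted p up to 0.0812). It ended with the replicate block (adjusted p = 0.0554) and with only the 6 arrays in the fit (adjusted p = 0.0621).

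A pair of germ cell genes were lower in both groups given the Nrf2b morpholino than with nrf2a alone. The gene nanos3, needed for germ cell maintenance, differed by -1.06 with nrf2b and -1.47 with both (adjusted p = 0.0299 and 0.00766), and ddx4 by -1.23 with nrf2b and at least 2.34-fold with both (adjusted p = 0.0480 and 0.0176). No list of germ cell genes was fixed, and these genes were singled out after their values were seen. The probe of ddx4 was well above background on 1 of 3 nrf2b arrays, so its size there is uncertain. The nanos3 values with nrf2a also lay above those of controls, without passing (limma adjusted p = 0.216). Without nrf2b array 1 the calls of nrf2b against nrf2a ended for both genes. Scan run and slide both parted the nrf2a arrays from these 2 groups, so neither can be told apart from the differences.

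In all 3 knockdowns 15 probes were called in the same direction against control. Those with a gene name were saa, btr31, dync1h1 (-0.69, -0.83 and -0.56 with nrf2a, nrf2b and both), pdcl3 (-0.99, -0.54 and -0.65), nceh1a, a probe of the peptide transporter gene tap2a that is not its brightest (lower in all 3), sacm1la (0.46, 0.64 and 0.53), the haptoglobin gene hp (0.51, 0.74 and 0.44) and xpnpep1 (0.30, 0.45 and 0.36). Even the brightest tap2a probe was not well above background on any knockdown array, so no size is given for the dimmer one. All 15 probes were set against the same 3 control arrays. These shared 1 slide that held no other group, so a slide difference cannot be told apart from a shared effect.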
